A study of Homo sapiens with 4 samples.

How the data were processed

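Single-cell replication sequencing reads the copy number of DNA along the genome of one cell, since a replicated stretch has more copies than an unreplicated one. Per the labels, 4 libraries of whole cells were made: a G1 and an S-phase library of HCT116, a human colorectal cancer line, and a G1 and an S-phase library of DKO1, the HCT116 derivative in which the DNA methyltransferase genes DNMT1 and DNMT3B are knocked out. Cells were sorted by DNA content, equal numbers of early, mid and late S-phase cells were pooled, and the pool was loaded on a droplet copy-number system, at a stock of 500 cells per uL for S phase and 60 cells per uL for G1, per the labels' protocols. The analysis used the S-phase cells of both lines. The G1 libraries were not analysed here.

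The authors deposited the values as state codes, 1 per bin of 80 kb and cell, and per the file headers each column is a cell of one of the lines. The name of the deposited table describes the codes as the binarised output of a hidden Markov model. The submitters' processing notes name Cell Ranger, SAMtools 1.10 and bedtools 2.26.0, and the builds hg19 and GRCh37. The model's software, its filters and the read depth per cell are not given in the sources used here, so the depth behind a call is unknown. The table has 27704 bins on 22 autosomes and no bin of the X chromosome. Chromosome 8 holds 21 bins. The last bin of chromosome 1 ends at 249200000, past the end of the last protein-coding gene of that chromosome in the GRCh38.p14 table, which is 248930191, and all coordinates are given as in the deposited table. Because no annotation of that build was used, bins were not assigned to genes, and the gene lists fixed beforehand were not run.

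The table does not define its 3 codes. Code 2 was read as replicated and code 1 as unreplicated, because across the 21 chromosomes with at least 100 bins the share of code 2 followed the density of protein-coding genes (Spearman's rho 0.85 in HCT116 and 0.88 in DKO1, across chromosomes, with densities from the GRCh38 table), and gene-rich chromosomes replicate early. Code 0 took 1.08% of the calls in HCT116 and 2.80% in DKO1 and was treated as not called. Bins called in at least 90% of the cells of both lines were used, which left 27142 bins (98.0%, or 2171 Mb). All 322 HCT116 and 207 DKO1 cells had a progress of 5 to 95% and were used. No doublet caller was run on these calls.

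S-phase progress of a cell is the percent of its called bins that were replicated. Cells were sorted into 10-point strata of progress, and the 6 strata from 20 to 80% that held at least 5 cells of each line were weighted equally. The standardised share of a bin is the weighted percent of cells in which it was replicated, so that the lines are compared at the same progress. Bins were split into 3 equal classes, early, middle and late, by the mean of both lines' shares. Replication width is the progress between 25% and 75% replicated on a logistic curve of state against cell progress minus bin time, with progress taken from the other chromosomes and bin time as 100 minus the line's own share. Pair discordance is the mean percent of bins that differed between 2 cells of a line, both at 40 to 60% progress and within 5 points of each other. Cells under 30% and over 70% progress were called early-S and late-S cells.

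Each line is 1 S-phase library, so no test between the lines was made and no p-value is given. Cells are not replicates. Exact binomial (Clopper-Pearson) 95% intervals cover counting error of cells only. As a measure of repeatability, the cells of each line were split 20 times into 2 equal parts. Cells were ordered by progress, and from each 2 neighbours 1 was drawn at random for each part. These random parts are thus matched in progress, and the spread between them leaves out differences in progress. The regions named were chosen by a rule of size fixed before the data were examined: runs of at least 5 bins, bridging at most 1 missing bin, in which every bin's standardised share differed in the same direction by at least 15 points, ranked by the sum of the differences, with the 10 highest in each direction. The functions were tested on simulated data with the real cells' progress and 27142 bins. Simulated widths of 15 in HCT116 and 20 in DKO1 came out as 26.7 and 31.0 by the definition above, and as 16.0 and 20.4 when bin time was put on the 20 to 80% scale of the strata, so this second form is printed beside the first. In that simulation, the wider spread and a few shifted regions alone gave a difference of -2.56 points in early bins and 2.95 points in late bins. In the simulation with equal widths of 15 the fitted widths differed by 0.25. Only shifted regions of intermediate timing were scored, and an overlap of 1 bin in the right direction counted as found. By this score 11 of 12 were found with unequal widths and 15 of 15 with equal widths. Regions called where none was shifted were not counted. Most of the named regions higher in DKO1, and some of the lower ones, lay outside the scored range in HCT116, so recovery of such regions was not shown.

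Alternatives fixed beforehand changed the cells, bins or chromosomes kept, the number of cells, the strata, the bin classes and the timing of bins. Counting code 0 as unreplicated, keeping only cells with code 0 in at most 1% of bins, the second scale of bin time, and reading the width from the observed curve were chosen after seeing the data. Scripts used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9.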

Results

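Replication states of single S-phase cells were compared between HCT116, a human colorectal cancer cell line, and its derivative DKO1. Per the labels, the DNA methyltransferase genes DNMT1 and DNMT3B are knocked out in DKO1. DNMT1 copies methylation onto new DNA strands, and DNMT3B can methylate unmethylated sites. Whether any of either enzyme remains in DKO1 was not examined. The table held 322 HCT116 cells and 207 DKO1 cells from 1 S-phase library per line, each called as replicated or unreplicated in 27142 autosomal bins of 80 kb. The median cell had replicated 52.7% of its called bins in HCT116 (quartiles 39.5 and 63.1%) and 48.8% in DKO1 (quartiles 39.97 and 59.6%). Progress ran from 17.3 to 77.6% in HCT116 and from 9.49 to 78.5% in DKO1, so the first and last parts of S phase were thinly covered. There were 35 HCT116 and 12 DKO1 cells under 30% progress, and 19 and 10 cells over 70%.

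**Figure D1:**
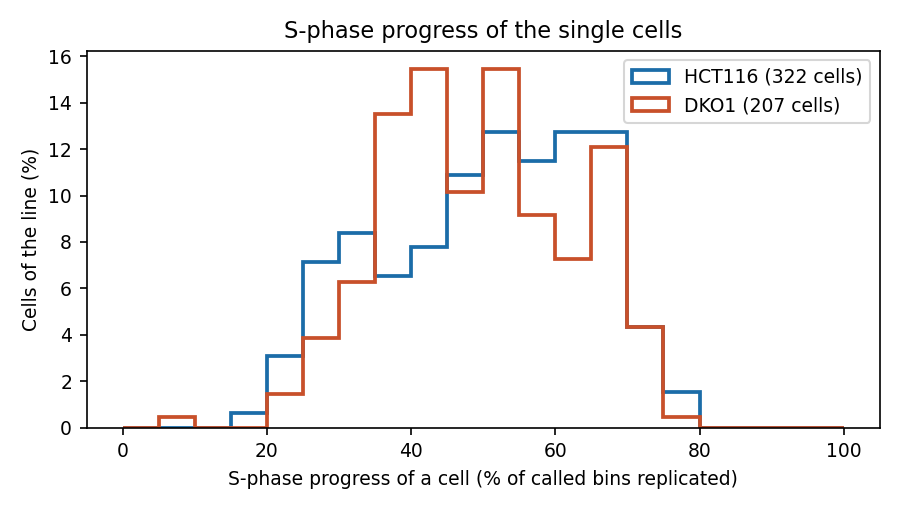
Histogram of S-phase progress (percent of called bins replicated, x axis, in steps of 5 points) as the percent of each line's cells (y axis) for the 322 HCT116 and 207 DKO1 cells. Both lines lie mostly between 20 and 80%, with medians of 52.7% in HCT116 and 48.8% in DKO1.

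The first comparison asked whether the genome replicates in the same order in both lines. The order was largely shared. Among the 21 chromosomes with at least 100 bins, the mean standardised share was highest on chromosome 22 (79.8% in HCT116 and 83.2% in DKO1), chromosome 17 (73.1 and 73.5%) and chromosome 19 (68.0 and 72.7%). Chromosome 22 rests on 163 used bins. Chromosomes 19 and 17 have the highest density of protein-coding genes. The next densest, chromosomes 11 and 16, had middling shares of 51.8 and 55.1% and of 48.8 and 52.1%. The lowest shares in HCT116 were on the gene-poor chromosomes 13 (38.1 and 41.6%) and 18 (39.0 and 36.0%). Gene density was used to read the codes, so its relation to the shares is no separate support for that reading. Across bins, which are not independent replicates, the shares of the lines correlated with Pearson's r of 0.953 and Spearman's rho of 0.951. The cells of each line were also split at random into 2 equal parts matched in progress. The parts of one line correlated with a mean r of 0.994 in HCT116 and 0.983 in DKO1, and parts of different lines with 0.948. The median absolute difference between parts of different lines was 5.92 percentage points per bin, against 2.257 between the parts of HCT116 and 3.65 between those of DKO1.

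Late-replicating bins were replicated in more DKO1 cells than HCT116 cells, and early-replicating bins in fewer. The late class of bins (the latest of 3 equal classes) was replicated in a mean of 9.35% of HCT116 cells and 14.4% of DKO1 cells, 5.02 points more. The early class was replicated in 89.9% of HCT116 cells and 86.7% of DKO1 cells, a difference of -3.19 points, and the middle class in 50.3 and 48.3%, a difference of -1.98 points. In the 2 parts of one random split of the cells the differences were 4.44 and 5.06 points in the late class and -3.48 and -2.83 points in the early class. In the middle class they were -0.32 and -2.31 points, so the size of that difference varied between the parts. By decile of bins, counted from the latest, the highest difference was 6.38 points in decile 3, where the share was 13.9% in HCT116 and 20.3% in DKO1, and the lowest was -5.01 points in decile 7, where it was 71.7 and 66.7%. The SD of the shares across bins was 34.7 points in HCT116 and 31.4 points in DKO1. With only cells that had code 0 in at most 1% of bins, of which 205 HCT116 and 77 DKO1 cells lay in the strata from 30 to 70% that could still be used, the late class differed by 2.57 points and the early class by -1.86, against 4.63 and -3.39 with all cells of those strata. The remaining settings gave differences from 3.68 to 6.41 points in the late class, from -4.73 to -1.51 in the early class and from -4.35 to -0.34 in the middle class: the early value was -1.51 with bins called in at least 99% of cells and the middle value -0.34 with code 0 as unreplicated and -4.35 without matching of progress. Simulated cells with the progress of all real cells and no change of bin times outside a few regions gave 2.95 points in the late class and -2.56 in the early class, with a smaller gap in spread between cells than the real one (fitted widths on the scale of the strata of 15.99 and 20.36 points, against 15.9 and 21.4), so these values do not tell how much of the real differences the spread accounts for.

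The next comparison asked how closely single cells keep to their line's order. DKO1 cells differed more from each other than HCT116 cells did. A pair of mid-S HCT116 cells at matched progress differed in 17.1% of bins on average (138 cells, 4124 pairs) and a pair of DKO1 cells in 23.1% (104 cells, 2329 pairs), 1.35 times as many. The excess was larger in early and late bins than in middle ones: in the early class of bins pairs differed in 6.44% of bins in HCT116 and 13.5% in DKO1, in the late class in 8.29 and 14.4%, and in the middle class in 36.5 and 41.2%. Among 104 mid-S cells of each line, 26.3% of bins in HCT116 and 36.0% in DKO1 were in an intermediate state, replicated in 20 to 80% of the cells, a measure chosen after seeing the data. Among cells with code 0 in at most 1% of bins, pairs differed in 15.96% of bins in HCT116 and 20.2% in DKO1.

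The replication width fitted with bin time from 0 to 100 was 26.0 points in HCT116 and 31.1 points in DKO1. In simulated cells this definition returned 26.7 for a width of 15, so these widths overstate the progress a bin itself takes. In random parts of the cells the gap between the lines ran from 3.63 to 5.52 points. With bin time on the scale of the strata, the widths were 15.9 and 21.4 points, a ratio of 1.35. On that scale, bins whose time lay 30 to 40 points ahead of the cell's progress were already replicated in 1.64% of HCT116 calls and 3.62% of DKO1 calls, and bins 30 to 40 points overdue were still unreplicated in 1.54 and 4.87%. All 21 chromosomes with at least 100 bins had a larger width in DKO1. The gap was largest on chromosome 14, with 25.3 points in HCT116 and 35.8 in DKO1, followed by chromosome 13 (27.3 and 36.5) and chromosome 11 (25.1 and 33.8), and smallest on chromosome 22 (27.3 and 27.8), but this order depended on cells with outlying chromosomes. On chromosomes 13, 11 and 14, in turn, 12.1, 11.6 and 9.66% of DKO1 cells had a replicated share more than 15 points from that chromosome's relation to cell progress, against 4.66, 0.311 and 2.80% of HCT116 cells. Without such cells the width stayed larger in DKO1 on all 21 chromosomes and the order changed: the gap was smallest on chromosome 11 (24.8 and 26.6) and largest on chromosome 9 (24.6 and 29.7), with 23.6 and 26.2 on chromosome 14, 25.02 and 29.9 on chromosome 13 and 21.003 and 25.4 on chromosome 22. Read from the observed curve instead of the fitted one, the widths with bin time from 0 to 100 were 31.5 and 33.2 points, a gap of 1.69, and on the scale of the strata 12.1 and 16.97 points. Among cells with code 0 in at most 1% of bins at 30 to 70% progress the gap of the fitted widths was 2.49 points, against 4.12 points over all cells at that progress.

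**Figure D2:**
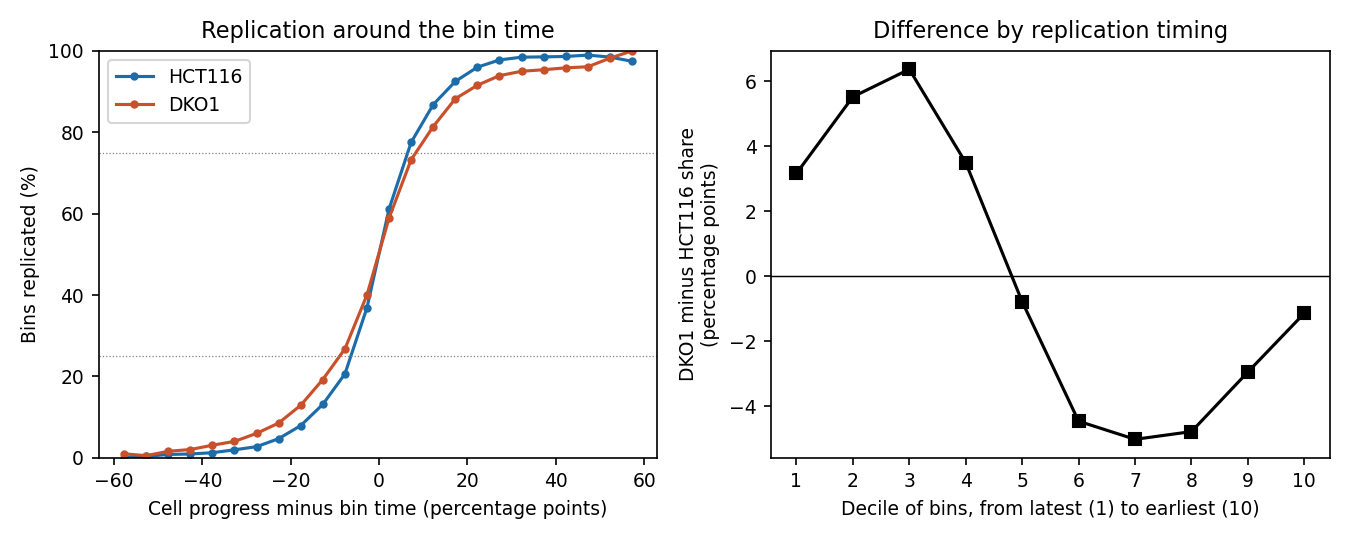
Left, percent of bins replicated (y axis) against cell progress minus bin time in percentage points (x axis), with bin time on the scale of the strata and dotted lines at 25 and 75%. The DKO1 curve is flatter, with fitted widths of 15.9 points in HCT116 and 21.4 in DKO1. Right, mean DKO1 minus HCT116 difference in standardised share (percentage points, y axis) by decile of bins from latest (1) to earliest (10) (x axis), from 6.38 points in decile 3 to -5.01 in decile 7.

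Bins replicated far out of the line's order were rare in both lines. The order came from the same cells, which can keep such bins out of the latest and earliest 20% and lower the values below. In early-S cells the latest 20% of bins (5429 bins) was replicated in a mean of 0.319% of bins in HCT116 (35 cells, range 0 to 2.69%) and 1.22% in DKO1 (12 cells, range 0.0377 to 3.67%). In late-S cells the earliest 20% of bins was still unreplicated in 1.01% of bins in HCT116 (19 cells, range 0 to 3.96%) and 2.80% in DKO1 (10 cells, range 0.165 to 8.40%). By a limit of 1% chosen after seeing the data, more than 1% of these early bins were unreplicated in 5 of 19 HCT116 cells (26.3%, exact interval 9.15 to 51.2%) and 6 of 10 DKO1 cells (60.0%, 26.2 to 87.8%). More than 1% of the late bins were replicated in 3 of 35 HCT116 cells (8.57%, 1.804 to 23.1%) and 3 of 12 DKO1 cells (25%, 5.49 to 57.2%). These differences rest on few cells of 1 S-phase library per line and were not tested. Progress was not matched in them. Its median was 25.9% in HCT116 and 27.7% in DKO1 among early-S cells, and 72.4 and 71.6% among late-S cells. Both offsets could raise the DKO1 values. Among cells with code 0 in at most 1% of bins, of which DKO1 had 3 early-S and 2 late-S cells, the means were 0.281 and 0.268% in early-S cells and 1.03 and 1.42% in late-S cells. With bins called in at least 99% of cells they were 0.159 and 0.777% in early-S cells and 0.375 and 1.02% in late-S cells, and with the 20% of bins taken from the ranking of the other line 0.535 and 1.88% in early-S cells and 1.01 and 4.05% in late-S cells.

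The genome of DKO1 cells was cut into somewhat fewer stretches. Along the autosomes of mid-S cells the state switched a median of 1260.5 times in HCT116 (quartiles 1185 and 1340) and 1150.5 times in DKO1 (quartiles 1045 and 1273). Among cells with code 0 in at most 1% of bins the medians were 1265 and 1206.

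The last comparison asked where along the chromosomes replication shifted. The 20 regions named, of 1.52 to 2.56 Mb, were picked for large differences in every bin. The region with the largest loss lay on chromosome 1 from 198640001 to 200480000, where the standardised share was 70.3% in HCT116 and 25.8% in DKO1, a difference of -44.5 points. Most of that region was replicated in 76.4% of 322 HCT116 cells (exact interval 71.4 to 80.9%) and in 13.2% of 205 DKO1 cells (8.86 to 18.6%). Such counts of cells, here and below, were not matched in progress. Without matching, the difference in share of this region was -49.7 points. On chromosome 12 from 88160001 to 89760000 the share was 85.7% in HCT116 and 48.3% in DKO1, and on chromosome 1 from 55600001 to 57600000 it was 72.7 and 37.3%. The other regions lower in DKO1 lay on chromosome 7 from 120240001 to 121840000 (66.7 and 34.0%), on chromosome 1 from 218080001 to 220080000 (68.6 and 37.8%) and from 246240001 to 247840000 (60.6 and 34.9%), on chromosome 20 from 51840001 to 53360000 (66.6 and 38.6%), on chromosome 11 from 27120001 to 29680000 (78.7 and 51.1%), on chromosome 12 from 116240001 to 117840000 (84.8 and 58.5%) and on chromosome 4 from 110400001 to 112320000 (60.9 and 38.5%). In HCT116 all 10 were replicated in most cells, with a mean share of 71.5%, against 40.5% in DKO1.

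**Figure D3:**
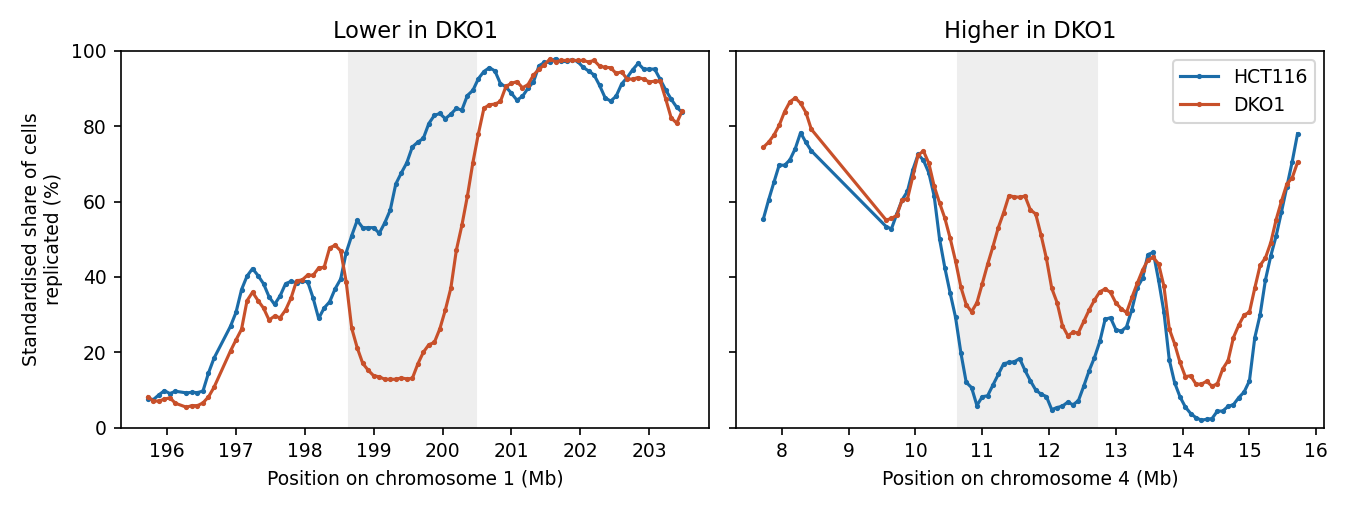
Standardised share of cells replicated (percent, y axis) per 80 kb bin along chromosome 1 (left) and chromosome 4 (right), positions in Mb as in the deposited table (x axis), with the regions at the head of each ranking shaded and 3 Mb on either side. Within the shaded stretches the lines stand apart, at 70.3% (HCT116) and 25.8% (DKO1) on chromosome 1 and at 11.4 and 42.1% on chromosome 4.

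The 10 regions higher in DKO1 were late in HCT116, with a mean share of 13.9%, and reached 40.7% in DKO1. The difference was largest on average on chromosome 4 from 22720001 to 24400000, where the share was 9.06% in HCT116 and 43.8% in DKO1, and where most of the region was replicated in 4.75% of 316 HCT116 cells (2.68 to 7.71%) and 42.4% of 203 DKO1 cells (35.5 to 49.5%). On chromosome 4 from 10640001 to 12720000, the region ranked first by summed difference, the share was 11.4 and 42.1%. On chromosome 2 from 16720001 to 19120000 it was 8.73 and 33.8%. Chromosome 6 held a region from 71920001 to 73680000 (13.6 and 41.8%), another from 139920001 to 142160000 (6.85 and 27.5%) and another from 38800001 to 40320000 (25.6 and 51.0%). The others lay on chromosome 9 from 117600001 to 119280000 (14.3 and 42.1%), on chromosome 13 from 109200001 to 110960000 (22.8 and 47.7%), on chromosome 10 from 116000001 to 117920000 (18.6 and 41.1%) and on chromosome 3 from 18400001 to 19920000 (8.22 and 35.9%).

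For all 20 regions the exact intervals of the lines did not overlap, and the difference had the same sign in both parts of a random split of the cells, by at least 18.0 points in each. These are the extremes of a ranking on the same cells, which inflates their size. The intervals take no account of the choice, of variation between cultures or of differences in progress between the lines. Both parts of the split consist of the cells that chose the regions, so neither the shared sign nor the separate intervals are independent support. With only cells with code 0 in at most 1% of bins, in the strata from 30 to 70%, the 10 higher regions differed by 18.7 to 36.6 points and the 10 lower regions by -49.5 to -23.5 points. No region covered more than 2.73% of its chromosome's bins. The differences of whole chromosomes ran from -3.04 points on chromosome 18 to 4.71 points on chromosome 19, with 11 chromosomes higher and 10 lower in DKO1.

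**Figure D4:**
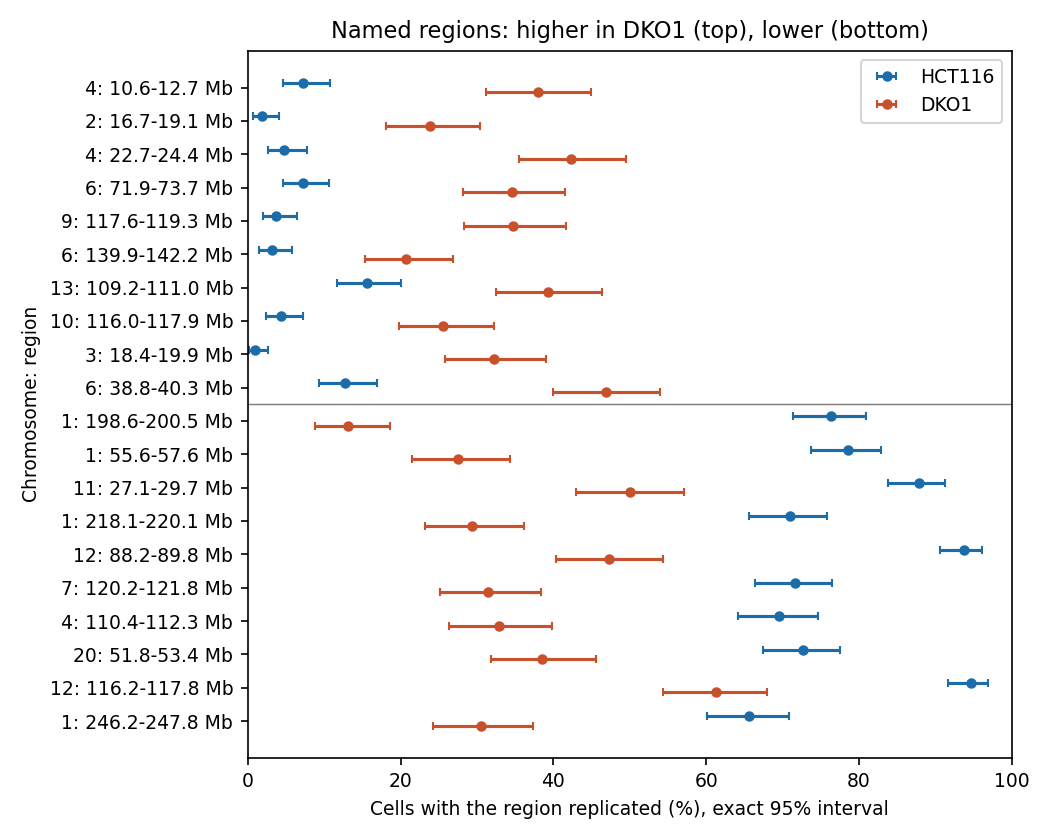
Percent of cells in which most of each named region was replicated (x axis, points, with exact 95% binomial intervals as bars that cover counting error only) for the 10 regions higher and the 10 lower in DKO1 (y axis, chromosome and position in Mb). The intervals of HCT116 and DKO1 do not overlap in any of the 20 regions, which were chosen for large differences in the same cells. Cells were not matched in progress here.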

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

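The tests on code 0 and on pairs of cells were chosen after the results were seen. The setting that kept only cells with little code 0 was chosen after seeing the data. The condition on the gap in replication width in these cells was set before that gap was seen.

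Code 0, which the comparisons leave out, was flagged because it was more frequent in DKO1 than in the parental cells. Outside bins that most HCT116 cells lack, it took 2.59% of the calls in DKO1 and 0.860% in HCT116, 3.01 times as much. A run of at least 50 such bins (4 Mb) occurred in 76.8% of 207 DKO1 cells (159 cells, exact interval 70.5 to 82.4%) and in 37.6% of 322 HCT116 cells (121 cells, 32.3 to 43.1%). Of the 0-coded bins, 82.0% in DKO1 and 75.9% in HCT116 lay in runs of at least 25 bins (2 Mb). Long runs held most of them in both lines, so run length does not tell thin coverage from losses of long segments in single cells. Both stay open, since the read counts per cell were not used here. Code 0 is not defined, so unreplicated DNA is a further reading that stays open. By chromosome, code 0 was most frequent on late-replicating chromosome 13 (2.61% of HCT116 and 6.45% of DKO1 calls). It was least frequent on chromosome 17 (0.0913 and 0.355%), where shares were high. Chromosome 18, also late, had 1.12 and 1.29%. The windows of 5 Mb with the largest excess lay on chromosome 4 at 185 to 190 Mb, with 12.6% of DKO1 calls and 3.39% of HCT116 calls, and on chromosome 13 at 90 to 95 Mb, with 12.8 and 3.67%.

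The larger spread between DKO1 cells is a pattern that poor cells or aneuploidy might produce. Each chromosome of a cell that departed by more than 15 points from its relation to progress was left out. These were 2.34% of those in HCT116 and 5.38% in DKO1, over all 22 chromosomes. Chromosome 8 has 11 used bins, so few bins could move its share that far. Leaving these chromosomes out reduced the gap in replication width from 5.13 to 3.22 points. That is above 50% of the gap (2.57) by slightly more than the spread between random equal parts of the cells (0.54). Whole-chromosome copy number is therefore unlikely to be the whole cause but could account for part. In the 6141 bins away from borders of timing domains the gap was 4.53 points, which argues against blurred borders. Among cells with code 0 in at most 1% of bins, which could be compared at 30 to 70% progress only, the gap in width was 2.49 points. The condition set beforehand for poor cells as the cause, a gap under 50% of that over all cells (2.57), was thus met. It was met by less than the spread (0.54), and against cells of a wider range of progress. The value lies over 50% of the gap of 4.12 points over all cells at the same progress (2.06), a reference chosen afterwards, also by less than the spread. It therefore neither establishes nor excludes poor cells as the cause. The gap between pairs was 4.19 points of the 5.97 over all cells, more than 50% of it (2.99), so poor cells may account for part of the excess. Smaller copy-number changes and the read depth of each cell stay open, since neither the G1 libraries nor read counts were analysed. The knockouts of DNMT1 and DNMT3B and any other difference between the cultures stay open too, since 1 S-phase library per line cannot separate them.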

How the results depend on the processing

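Settings on code 0, the scale of the strata, the observed curve and the chromosome differences were chosen after seeing the data. None of the results changed direction between the lines except the early-S late bins, whose gap was -0.013 points in cells with little code 0. The gap in replication width was positive in all 15 settings (1.69 to 9.47 points), that of pairs in all 8 (4.19 to 6.28), and DKO1 had fewer switches in all 9 (-114 to -49). These counts include the main setting. Keeping all cells, or those with progress of 10 to 90%, repeated its widths, pairs and switches, so these settings add no support. A value was taken as moved where it shifted by more than the spread between random equal parts of the cells. For the progress medians this spread is narrow because the parts were matched in progress. Values are given for HCT116 and then DKO1. Keeping all cells changed nothing, since none lay outside 5 to 95%. With bins called in at least 99% of cells (8044 bins), the progress medians were 61.2 and 57.4%, r was 0.948, the early difference -1.51 points, the DKO1 width 30.1, the HCT116 pair discordance 18.1%, the switches 477 and 428, and the highest minus the lowest chromosome difference 11.6 points against 7.75. Without chromosomes 8, 10, 16 and 17 the medians were 51.7 and 47.8% and the switches 1110 and 1025, since fewer bins were counted. With equal numbers of cells drawn per stratum of progress (206 per line), which matches progress too, the medians were 49.5 and 49.2%. Without progress matching the middle difference was -4.35, the late one 3.68 and the widths 28.1 and 33.4. Strata of 20 points gave r of 0.956, an early difference of -2.22 and widths of 27.1 and 32.4. Classes by the HCT116 share gave -4.73 in early and 6.41 in late bins. Bins timed by the mean of both lines gave widths of 24.5 and 34.0. Removing runs of 1 bin gave 1167 and 1087.5 switches. Code 0 as unreplicated gave medians of 52.4 and 48.3%, r of 0.957, an early difference of -3.98, a middle one of -0.34, widths of 28.1 and 33.2 and pair discordances of 17.9 and 24.1%. Cells with little code 0 gave an HCT116 median of 53.2%, r of 0.957, an early difference of -1.86, a late one of 2.57, an HCT116 width of 29.0, pair discordances of 15.96 and 20.2%, and 1206 switches in DKO1. Those shares and widths rest on strata from 30 to 70% only, where all cells gave widths of 29.99 and 34.1 points and differences of -3.39 in early and 4.63 in late bins. The scale of the strata gave widths of 15.9 and 21.4, the observed curve 31.5 and 33.2, and both together 12.1 and 16.97. The named regions, which were chosen on the same cells, kept their direction in every setting run on them. The gene lists were not run, for want of an annotation of the build, and no paired analysis was possible because each line is 1 S-phase library. Depth per cell is unknown, and progress outside 20 to 80% rests on few cells.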

Other observations

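Bins within 5 Mb of the first or last bin of a chromosome in the table were replicated in slightly more DKO1 cells than HCT116 cells, with a mean standardised share of 55.9% in DKO1 and 54.2% in HCT116 over 1916 bins, a difference of 1.66 points. Elsewhere the difference was -0.18 points over 25226 bins. The replication width was 32.3 points in DKO1 and 26.1 in HCT116 near the ends, and 31.0 and 26.0 points elsewhere.

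The named regions took intermediate shares in DKO1, and a mixture of cells with and without the change is a candidate explanation. Such shares are not particular to these regions: bins of decile 5 had a mean share of 43.1% in HCT116 and 42.4% in DKO1. An intermediate share is therefore no sign of a mixture in itself. All tests in this paragraph were set before their results were seen. If a subpopulation carried the change at all regions, their states would go together across cells once progress is removed. The mean correlation between regions on different chromosomes was 0.028 across DKO1 cells for the lower regions (38 pairs of regions, 0.082 across HCT116 cells) and 0.0043 for the higher regions (41 pairs, 0.011 across HCT116 cells), which argues against a shared subpopulation. Whether these regions varied more from cell to cell than other bins of like share was not tested. A fixed copy-number difference was first expected to hold the share of a region constant through S phase. From cells at 20 to 40% progress to cells at 60 to 80% the median DKO1 share of the higher regions rose by 47.5 points and that of the lower regions by 44.5 points, against 20.8 and 41.9 points in HCT116. Both DKO1 rises met the condition set beforehand against a fixed difference. However, a gain or loss shifts the signal without stopping replication, so the share of such a region could rise too, and the rises do not decide. A fixed copy-number difference stays open because the G1 libraries, which would show it, were not analysed. The knockouts of the methyltransferase genes and a drift between the cultures stay open, since 1 S-phase library per line cannot separate them.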
